A study of Caenorhabditis elegans with 2 samples.

How the data were processed

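ChIP-seq of CEH-9 carrying a GFP-FLAG tag was measured in 2 biological replicates of whole late embryos, the only group of the series. The replicate numbers are those of the labels. Each replicate has its own deposited relaxed peak list, and the series has a pooled relaxed list and a list of peaks that passed an irreproducible discovery rate (IDR) threshold, all in the ce11 and ce10 builds. Per the labels, each replicate list was derived from that replicate's alignments and a control, the pooled list from both replicates and the control, and the IDR list from the 3 relaxed lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The control libraries were not analysed here.

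The authors deposited a signal value per peak, which is the peak's height on the scale of their peak caller and differs in scale between lists, so it was used only by rank within a list. The authors also deposited a −log10 q per peak, which reached 2.49 in the ce11 reproducible list and was not tested further. The score column is 0 throughout, and no read counts are given. Each relaxed list holds 30000 lines, a fixed length, so membership alone is not informative. In ce11 the 207 reproducible peaks are exactly the 207 strongest of the pooled list, and in ce10 the same holds for all 217. Most entries are 420 bp wide in the ce11 reproducible list, and 8 differ. Depth is unknown, and the exact binomial (Clopper-Pearson) intervals cover the counting of peaks or genes only.

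Genes came from Ensembl release 115 on the same assembly as ce11, with tRNA isotypes from the RefSeq annotation. The ce10 lists were counted and compared with each other but not annotated, since no ce10 genome was used here. Summits were taken from the files. A TSS was called near within 1 kb, and a summit was assigned to the nearest protein-coding TSS within 2 kb. Random placements (10000) kept the number of peaks per chromosome. Gene lists (22) and k-mers (16) were fixed before the data were examined, and 5 listed names had no match in the annotation. Each gene list was compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, at a threshold of 0.05. Motif windows ran 75 bp to each side of the summit. Their background was 5 windows per peak, matched on GC content in bins of 5 percentage points, at pooled-list summits over 1 kb from any reproducible peak. The class of small RNA genes and its distance of 100 bp were chosen after the data were seen. Repeated sequence was measured with words of 36 bases, an assumed read length, since the read length is not given in the sources used here. A B box was searched as GWTCRANNC on either strand, in the gene and 100 bp to each side.

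Genes were named by a rule fixed before the data were examined. It takes the nearest protein-coding genes of the 25 strongest peaks, up to 4 members of each list by signal, ceh-9 and unc-119, and the 5 most enriched 6-mers. The RNA genes and the collagen genes past the first 4 are outside the rule and were named after their values were seen. Whole embryos were used, so no peak was assigned to a cell type.

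The tests were first run on simulated data, 20 runs each apart from the correlation. With nothing planted, the motif test called 0 of 320 k-mers and the gene list test 0 of 440 lists across 19973 genes. The motif windows for this came from the rest of the pooled list, where 0.997% of summits lay at small RNA genes. They lacked the many related tRNA windows of the real list, so this rate need not hold for it. The chromosome test called 2 chromosomes over its 20 runs, and the location test 0 runs. With TAATTA planted in 20% of windows, 8 homeobox genes planted, 30% of peaks placed on X or 30% of summits moved to a TSS, the planted signal was called in 20 of 20 runs each. A simulated correlation of 0.5 was returned as 0.51 in a single draw, which lacked the choice of peaks by pooled signal.

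Alternatives covered the build, the stronger part of the list, each replicate alone, distances, windows and backgrounds. No untagged strain and no second condition were analysed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.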

Results

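The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for CEH-9, a homeobox transcription factor of Caenorhabditis elegans. The worms were of strain OP202, which carries an integrated transgene for CEH-9 with a C-terminal GFP-FLAG tag. Chromatin was sheared by sonication and precipitated with an antibody against GFP. Whole late embryos of mixed sex were collected 4.75 h after synchronization by egg bleaching. The series has 1 group of 2 biological replicates and no second condition, so the question it addresses is where the tagged protein is found along the genome. The lists hold no read counts, so sequencing depth is unknown. Coordinates below are those of the ce11 build.

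The authors' list of reproducible peaks held 207 entries, and they covered 0.0849 Mb. The strongest of them lay at genes for small non-coding RNAs. A small RNA gene here means a gene for a transfer RNA (tRNA), a small nucleolar RNA (snoRNA), a small nuclear RNA (snRNA), or the RNA of RNase P, RNase MRP or the signal recognition particle. Of the 207 summits, 129 (62.3%, exact 95% interval 55.3 to 68.9%) lay within 100 bp of such a gene. Random placement on the same chromosomes gave 0.349% (p = 0.0002, two-sided permutation test, the smallest that 10000 placements can give). Among the other 29685 summits of the pooled list, those over 1 kb from any reproducible peak, the share was 0.997%. This class of genes was chosen after the peak lists had been seen. Peak signal is the authors' own value and is used only to rank peaks within a list.

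The highest signals belonged to snoRNA genes, whose RNAs guide the chemical modification of other RNAs. The 6 strongest peaks were all at snoRNA genes, and 15 of the strongest 25 were. The peak of highest signal (416) spanned positions 12303502 to 12303815 of chromosome V, in an intron of a protein-coding gene. Its summit lay inside the snoRNA gene C51F7.4 at 12303599 to 12303693. The second (signal 392) was on chromosome V at 8500433 to 8500706, also in an intron, with its summit inside the snoRNA gene ZK994.7. The third (signal 366) was on chromosome II at 11960686 to 11960967, beside the snoRNA gene W03C9.9 and between protein-coding genes. In all, 37 summits lay at snoRNA genes, and 38 of the 346 annotated snoRNA genes (11%, exact 95% interval 7.89 to 14.8%) had one. Of these 37 summits, 32 were upstream of the RNA's 5′ end, 3 were inside the gene and 2 were downstream. The median position was 47 bp upstream (-47), and upstream exceeded downstream (p = 6.94e-08, two-sided exact binomial test).

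Of the small RNA classes, tRNA genes had the most summits, 86 (41.5%, exact 95% interval 34.8 to 48.6%) against 0.198% at random (p = 0.0002, permutation test). Genes annotated as other non-coding RNA were near as many, 86, but only 15 of those summits were at none of the other RNA classes. The tRNA genes dominated just below the snoRNA peaks. Their share was 28% of the strongest 25 peaks, 68% of ranks 26 to 50 and 58% of ranks 51 to 100. The strongest was a leucine tRNA gene, C04A11.t1, at 13665555 to 13665673 of chromosome X (signal 226). It was followed by a glycine tRNA gene, M02F4.t1, at 3036164 to 3036235 of chromosome X (signal 220). Of the 612 annotated tRNA genes, 91 (14.9%, exact 95% interval 12.1 to 17.9%) had a summit. Summits at tRNA genes were mostly inside the gene (53 of 86), with 29 upstream and 4 downstream.

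Other small RNA genes with a peak have known roles in RNA processing and protein targeting. The gene rpr-1, which encodes the RNA of RNase P, had a peak of rank 26 (signal 155) on chromosome I at 13463765 to 13464184. The gene mrpr-1, for the RNA of RNase MRP, had one of rank 59 (signal 123) on chromosome II at 7200049 to 7200468. The signal recognition particle RNA gene srpr-2.2 had one of rank 122 (signal 89.2) on chromosome III at 5031366 to 5031785. Of the 7 annotated genes of this class 3 had a peak (exact 95% interval 9.90 to 81.6%). So did 3 of 129 snRNA genes, whose 3 summits (1.45%) compare with 0.0352% at random (p = 0.0002, permutation test). None of 20 rRNA genes had one (exact upper bound 16.8%). The single RNA genes given here and above were named after their values were seen.

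**Figure D1:**
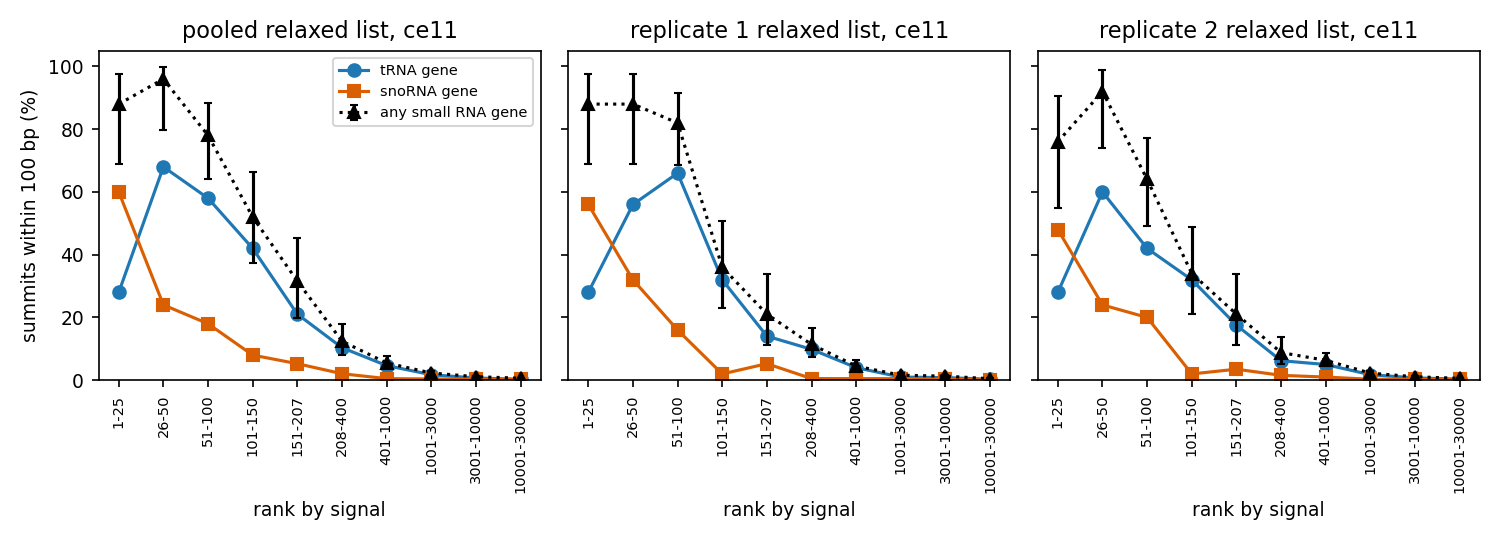
Share of peak summits (%, vertical axis) within 100 bp of a tRNA gene, a snoRNA gene or any small RNA gene, by rank of signal (horizontal axis), in the pooled list and in each replicate's own relaxed list; bars on the triangles are exact 95% intervals. In the pooled list the share at any small RNA gene falls from 88% at ranks 1 to 25 to 0.64% at ranks 10001 to 30000, and both replicates show the same fall.

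Each replicate's own list had the same order of classes. Small RNA genes took 88% of the strongest 25 peaks of replicate 1 and 76% of those of replicate 2. They took 21.1% of ranks 151 to 207 in either replicate. In the pooled list the share was 31.6% at ranks 151 to 207 and 12.4% at ranks 208 to 400.

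Of the protein-coding genes nearest to the strongest 25 peaks, only col-85 was in a fixed gene list. These genes were F55C5.17, pxn-1 (a peroxidasin), W03C9.1, str-56 and sre-23 (chemoreceptors), cutl-18, C04A11.5, M02F4.2, hrg-5, T13C5.6, twk-5 (a potassium channel), T02E1.2 and lgc-21 (a ligand-gated channel). The others were Y43F8C.7, pamn-1, col-85 (a collagen), K07H8.7, F15G9.5, sulp-3, K12H4.5, mpk-2 (a MAP kinase), unc-41 (a synaptic vesicle recycling factor), chst-1, snx-17 (a sorting nexin) and F55A11.6. Of these 25 summits, 22 were at a small RNA gene, 2 were at genes annotated only as other non-coding RNA, and the one nearest to K12H4.5 (signal 171) was at neither. The distance to the nearest protein-coding transcription start site (TSS) ranged from 53 to 6986 bp, with a median of 1090 bp, and 8 of the 25 lay over 2 kb away.

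Across all 207 peaks, 101 summits (48.8%) lay within 1 kb of a protein-coding TSS, against 40.1% at random (p = 0.0118, two-sided permutation test). Against the rest of the pooled list, in which 45.1% of summits lay that near, it did not pass (odds ratio 1.16, p = 0.294, Fisher's exact test). Either replicate alone kept a higher share than random but did not pass, at 45.4% against 40.3% in replicate 1 (p = 0.16) and 47.3% against 40.4% in replicate 2 (p = 0.0512, permutation test). The 78 peaks away from small RNA genes had 60.3% near a TSS, against 40.7% at random (p = 0.0008, permutation test), 45.1% in the rest of the pooled list (odds ratio 1.84, p = 0.00852, Fisher's exact test) and 41.9% of the 129 peaks at small RNA genes (odds ratio 2.1, p = 0.0145, Fisher's exact test). Coding exons held 6.28% of all summits against 24.1% at random (p = 0.0002, permutation test), and none of the 129 at small RNA genes lay in one. Of the other 78, 13 did (16.7% against 24.7% at random, p = 0.123, permutation test). That was fewer than the 31.0% in the rest of the pooled list (odds ratio 0.445, p = 0.00653, Fisher's exact test). More summits than at random lay between protein-coding genes, 53.1% against 37.7% (p = 0.0002, permutation test), with 51.9% at small RNA genes and 55.1% elsewhere. Introns held 38.2% against 33.3% (p = 0.15, permutation test), with 46.5% at small RNA genes and 24.4% elsewhere. The splits at small RNA genes were chosen after the data were seen.

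The question of how far the replicates gave the same peaks was asked at the 207 reproducible positions. A summit within 100 bp was among the 207 strongest of replicate 1 for 122 peaks (58.9%) and among those of replicate 2 for 143 (69.1%). It was in both for 88 (42.5%). Random placement gave 0.0468% for replicate 1 and 0.0442% for replicate 2. Signal ranks of the replicates correlated across the 188 peaks found in both lists (Spearman's rho = 0.52, p = 1e-05, permutation test, the smallest that 100000 resamples can give). Within the 123 peaks at small RNA genes rho was 0.59 (p = 1e-05, permutation test). Within the other 65 it was -0.021 (p = 0.867, permutation test). Peaks are not independent replicates, and the 207 peaks are the 207 strongest of the pooled list, which was made from the same libraries. In the next ranks of that list the same choice gave a rho of -0.66 across 157 peaks.

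**Figure D2:**
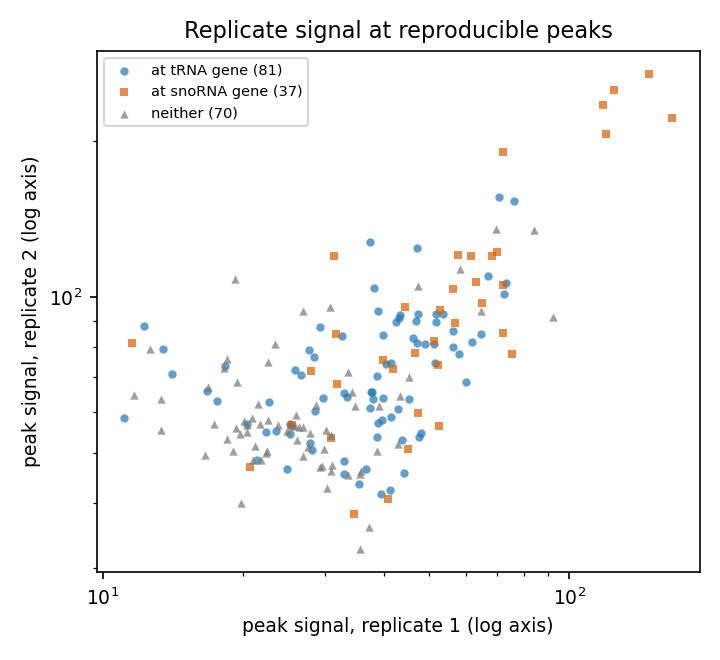
Authors' peak signal in replicate 2 (vertical, log axis) against replicate 1 (horizontal, log axis) at the 188 reproducible peaks listed in both replicates, each point 1 peak, coloured by the gene at its summit. The highest signals in both replicates are at snoRNA genes, and peaks at neither class sit mostly at the low end.

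Chromosome X held more peaks than its length gives. It had 57 of 207 (27.5%, exact 95% interval 21.6 to 34.2%) against 17.7% of the genome (adjusted p = 0.00289, two-sided exact binomial test, Benjamini-Hochberg over 6 chromosomes). The excess was at tRNA genes, of which X carries 276 of 612 (45.1%). Peaks at tRNA genes were on X in 45 of 86 cases (52.3%), and peaks elsewhere in 12 of 121 (9.92%), a difference with p = 1.77e-11 (Fisher's exact test). A tRNA gene on X had a peak in 17.4% of cases and one on an autosome in 12.8% (p = 0.137, Fisher's exact test). Chromosome V held 28 peaks (13.5%) against 20.9% of the length (adjusted p = 0.0237, exact binomial test). The call on V was lost under every alternative tried. Chromosomes I to IV did not pass the test.

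**Figure D3:**
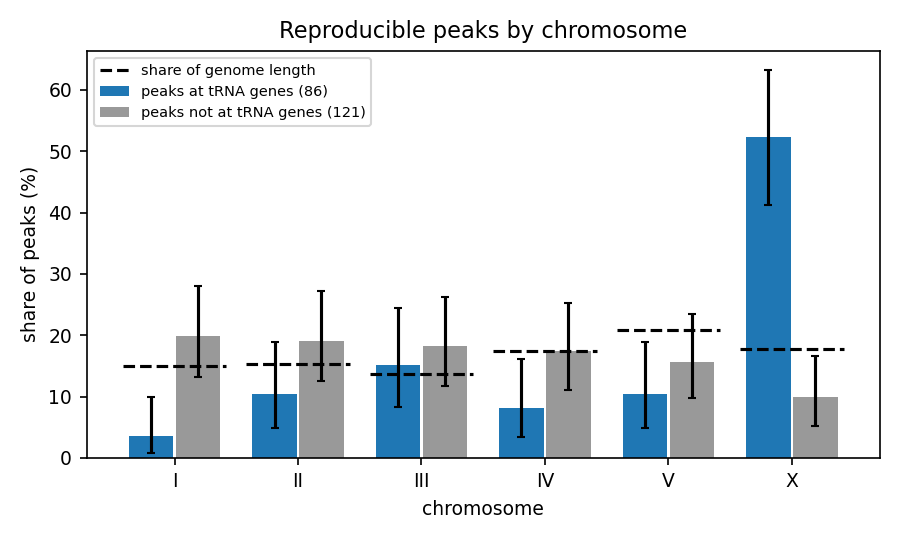
Share of reproducible peaks on each chromosome (%, bars with exact 95% intervals) for the 86 peaks at tRNA genes and the 121 others; dashes mark the chromosome's share of genome length. On X the peaks at tRNA genes reach 52.3% and the others 9.92%, against 17.7% of the length.

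To ask which genes lay beside the peaks, 147 summits were assigned to 145 of 19973 protein-coding genes with a TSS within 2 kb, and 22 gene lists fixed before the data were examined were tested. Cuticle collagen genes, which encode the worm's exoskeleton, were the only list past the threshold. Of 175 collagen genes, 9 had a peak (5.14%), against 0.687% of other genes (odds ratio 7.84, exact 95% interval 3.45 to 15.7, adjusted p = 0.000119, Fisher's exact test). The first 4 by signal were col-85 (176), col-181 (138), col-185 (96.8) and col-105 (89.7). The first 3 of these summits were at tRNA genes, and that of col-94 was at an snRNA gene. The peak of col-85 was in an intron on chromosome II at 12494494 to 12494913, and that of col-105 on chromosome IV at 1358067 to 1358486. The other 5 collagen summits, col-105, col-183, dpy-7, col-91 and col-51, were all in coding exons, 566 to 948 bp from the TSS. They made up 5 of the 13 summits in coding exons, and the GC content of their windows ranged from 57.6 to 74.8%. Without the peaks at small RNA genes the list kept 5 genes (odds ratio 11.2, adjusted p = 0.00311, Fisher's exact test). With the strongest peaks of replicate 1 alone it had 4 genes and did not pass (odds ratio 3.38, adjusted p = 0.667, Fisher's exact test). Nor did it in the stronger 104 peaks, with 3 genes (odds ratio 4.85, adjusted p = 0.3, Fisher's exact test). The collagen genes past the first 4 were named after their values were seen.

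No homeobox gene was assigned a peak (0 of 98), and the list holds ceh-9 itself. Random placement of the peaks gave 0.957 such genes on average, so 0 shows no depletion (exact upper bound of the odds ratio 5.29). Nor was any gene of the pan-neuronal (26), glial (19), pharynx (35), intestine (54), germline and P granule (55), Notch pathway (34), ribosomal protein (82), core histone (73) or heat shock (63) lists. For these lists random placement gave 0.172 to 0.386 genes each, so their absence is not informative here. The other lists had 1 to 3 genes each and did not pass (smallest adjusted p 0.652, Fisher's exact test). Nuclear hormone receptors had nhr-255 (signal 115) and nhr-41 (74.3). Other developmental transcription factors had ets-5 (143) and zip-2 (79.7). Neuropeptide genes had nlp-76 (137), flp-23 (87.3) and ntc-1 (80.5), the last encoding nematocin. Cell cycle genes had cye-1, which encodes cyclin E (144), and mdf-2, a spindle checkpoint gene (109). Single genes stood for the remaining lists. They were ser-2, a tyramine receptor (87.4), plx-1, a plexin (75.5), gcy-33, a guanylate cyclase (136), act-4, an actin (75.9), wrt-3 (129), vang-1 (85.2) and egl-17, a fibroblast growth factor (95.7). Of these 16 genes, the summits of nhr-255, nhr-41, ets-5, nlp-76, flp-23, cye-1, mdf-2, ser-2, gcy-33 and egl-17 were at tRNA genes, and that of wrt-3 was at a snoRNA gene.

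**Figure D4:**
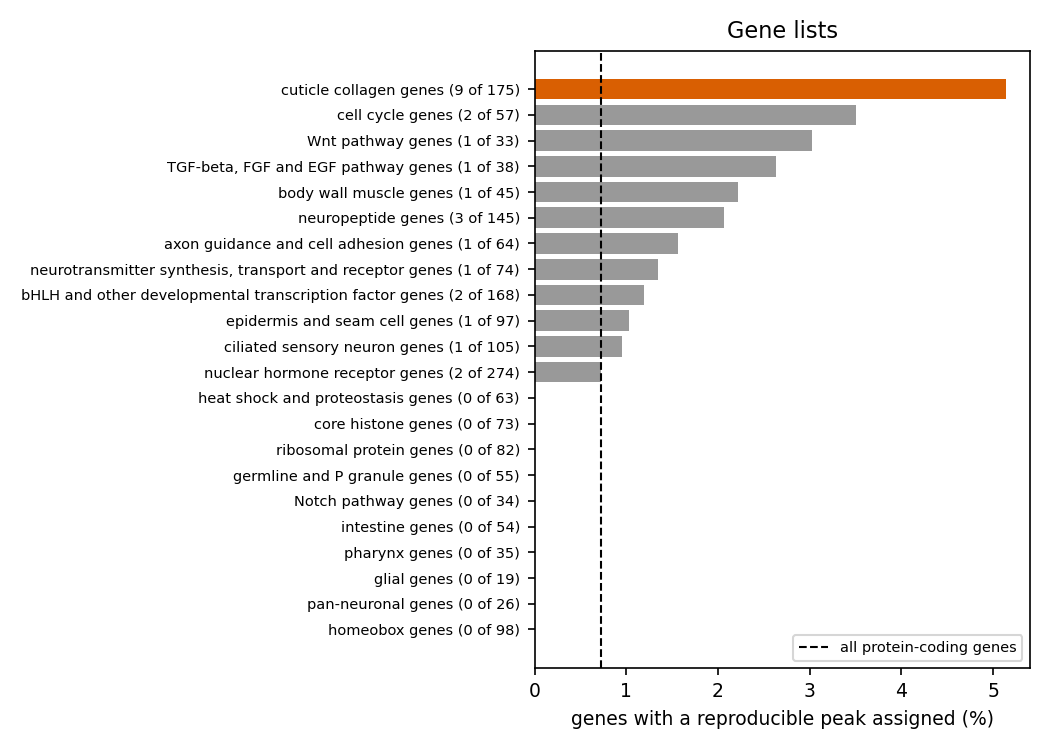
Share of the genes of each fixed list with a reproducible peak assigned (%, horizontal axis), with counts in brackets; the dashed line is the share among all protein-coding genes. The cuticle collagen list, at 5.14%, is the only one past the test.

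The homeodomain core sites TAATTA and TAATTG were rare at summits at small RNA genes, but neither alone passed the test there or at the others. In windows of 151 bp, TAATTA occurred in 4 of 207 (1.93%) and in 2.32% of 1035 GC-matched windows (adjusted p = 1, Fisher's exact test). TAATTG, a core bound by many homeodomains, occurred in 5 (2.42%) against 5.70% (odds ratio 0.41, adjusted p = 0.169, Fisher's exact test). In the 129 windows at small RNA genes TAATTA was in 0, against 2.17% of GC-matched windows (adjusted p = 0.327, Fisher's exact test). TAATTG was in 1, against 5.12% (adjusted p = 0.123, Fisher's exact test). In the 78 windows elsewhere the direction turned, with TAATTA in 4 (5.13% against 1.28%, odds ratio 4.14, adjusted p = 0.371, Fisher's exact test) and TAATTG in 4 (odds ratio 1.45, adjusted p = 0.922, Fisher's exact test). Against the flanks of the same peaks both were rarer at the summit (odds ratio 0.207 for TAATTA and 0.181 for TAATTG, adjusted p = 0.00251 and 0.000103, Fisher's exact test), a comparison not matched on GC content. TAATGA and TAATGG did not differ either, at 2.90% against 4.06% and 7.25% against 5.12% (adjusted p = 0.887 and 0.48, Fisher's exact test). Of the 16 fixed k-mers, only GCGCGC passed, which had been included as a GC-rich control. It occurred in 10.6% against 3% of windows (odds ratio 3.85, adjusted p = 0.00016, Fisher's exact test). It did not pass with replicate 1 alone (odds ratio 2.45) or in the stronger 104 peaks (odds ratio 2.58). Nor did it pass in the 129 windows at small RNA genes (7.75% against 4.96%, adjusted p = 0.361, Fisher's exact test). In the 78 windows elsewhere it did (15.4% against 4.87%, adjusted p = 0.0314, Fisher's exact test). The number of TAATTA and TAATTG matches did not correlate with signal across the 207 peaks (Spearman's rho = -0.046, p = 0.518, permutation test), and only 9 peaks had a match.

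Among all 2080 6-mers, 118 were more frequent at summits and 60 less frequent. The 5 with the smallest p were AGTGGT (30.4% of windows against 5.70%), GGTTCG (27.5% against 4.64%), GTTCGA (30.9% against 6.86%), TGGTTA (15% against 2.32%) and AGAGCG (20.3% against 4.93%), with adjusted p from 3.91e-18 to 5.86e-09 by Fisher's exact test. That test takes windows as independent, but tRNA genes are related in sequence. Of the 86 windows at tRNA genes, only 4 held no repeated sequence. These p-values, and the calls of 118 and 60 6-mers, therefore rest on fewer independent sequences than windows. AGTGGT and TGGTTA lie in the consensus around the A box, and GGTTCG and GTTCGA in that of the B box, the internal promoter elements of tRNA genes read by RNA polymerase III. GTTCGA was in 45 of 86 windows at tRNA genes (52.3%), in 15 of 37 at snoRNA genes (40.5%) and in 3 of 78 away from small RNA genes (3.85%). In those 78 windows alone, a smaller set, no 6-mer passed (smallest adjusted p 0.424, Fisher's exact test). In the 129 windows at small RNA genes alone, 3 of the 16 fixed k-mers passed. GAGAGA was more frequent (24.0% against 10.7%, adjusted p = 0.0022, Fisher's exact test) and CAGCTG less frequent (0.775% against 6.82%, adjusted p = 0.0184, Fisher's exact test). The homeodomain core TAATGG was more frequent (8.53% against 2.48%, adjusted p = 0.0173, Fisher's exact test), and 8 of its 11 matches lay inside a tRNA gene. The limit from related tRNA windows holds for these 3 calls too.

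The tagged gene had no listed peak. The gene ceh-9 (chromosome I, 565284 to 566588, minus strand) lay in a stretch of 43.7 kb without a summit in the pooled relaxed list. The stretch was 40.5 kb long in replicate 1 and 42.5 kb in replicate 2. By length it ranked 43 among the 29994 stretches between neighbouring summits of the pooled list, 21 in replicate 1 and 36 in replicate 2. The gene unc-119 (chromosome III, 10902641 to 10908935), which is mutated in the strain, had 4 pooled peaks within 2 kb of its TSS. The best of these ranked 7322 (signal 37.1), and none was in the reproducible list.

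**Figure D5:**
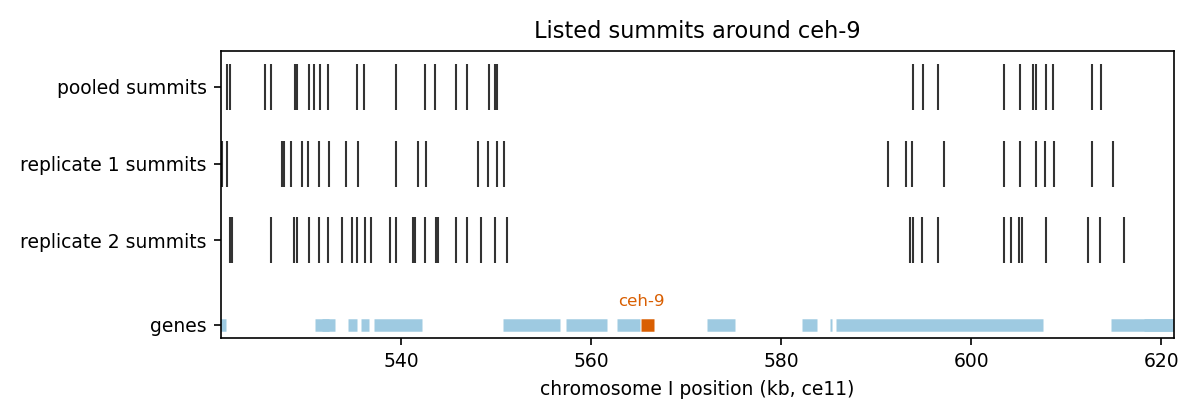
Summits of the relaxed ce11 lists (vertical lines; pooled, replicate 1, replicate 2) and protein-coding genes (bars, ceh-9 in orange) along chromosome I (kb). No list has a summit between positions 551101 and 591279.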

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

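Of 96 alternatives, 59 kept direction and side of the threshold, or stayed within the main value's interval or 1.5 times a count. Those on leaving out peaks at small RNA or tRNA genes, and all 8 on the share at small RNA genes, were chosen after seeing the data. That share stayed past its test in all 8, from 29.5% (summit inside the gene) to 83.7% (stronger 104 peaks). No paired analysis was possible because there is 1 group. A stricter IDR score was not run, since the score column is 0. Unless stated, the cause of a change was not tested, and unknown depth limits how small a peak the lists could hold.

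The stronger part of the list held 104 peaks by construction. The share of peaks among the strongest of both replicates was 35.3% at 50 bp, 56.0% with lists of 2N and 69.6% with 5N, longer lists giving more by construction. Without peaks at small RNA genes the replicate rho was -0.021. The TSS share lost its call at 500 bp (27.1%, p = 0.136, permutation test), in single replicates (45.4 to 47.3%), in the stronger 104 peaks (47.1%) and against the pooled list (odds ratio 1.16). Over its alternatives its p ranged from 0.0002 to 0.294 (permutation or Fisher's exact test). The X share fell to 9.92% without peaks at tRNA genes. The V share lost its call in single replicates (14.5 to 16.9%), against the pooled list (13.5%), in the stronger 104 peaks (12.5%), in ce10 (12.4%) and without tRNA peaks (15.7%).

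The number of gene lists called by Fisher's exact test was 0 to 1 in single replicates and 0 in the stronger 104 peaks, where 2 lists had an unadjusted p under 0.05 (1 list in replicate 1 alone). The collagen odds ratio was 3.38 to 7.78 in single replicates and 4.85 in the stronger 104 peaks. The number of k-mers called was 3 at 50 bp, 2 at 100 bp, 9 against flanks of the same peaks, 4 against unmatched windows, 1 to 2 in single replicates and 2 in the stronger 104 peaks. The odds ratio of TAATTA turned to 4.14 without peaks at small RNA genes (0.493 to 1.37 in single replicates). That of TAATTG turned to 1.45 (0.575 to 1.06 in single replicates). None of these turned values passed the test. TAATTG became a call for fewer matches at 50 bp (odds ratio 0.124), against flanks (0.181) and against unmatched windows (0.241), and TAATTA against flanks (0.207). GCGCGC lost its call in replicate 1 alone (2.45) and in the stronger 104 peaks (2.58).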

Other observations

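The B box comparison at reproducible peaks, the tests of the X excess and of the stretch around ceh-9, and the values in the next paragraph, were chosen only after the peak lists had been seen. The other tests of the peaks at small RNA genes rest on a class of genes that was itself chosen from those lists. Read length is unknown, so the words of 36 bases are an assumption, and another length can change the repeated-word tests. The rules for chance spacing and unplaceable sequence around ceh-9 were rewritten after their values had been seen.

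Peaks at tRNA genes were spread over the isotypes. Of 20 methionine tRNA genes 6 had a peak (30%), of 34 alanine genes 9 (26.5%) and of 27 glutamine genes 2 (7.41%), and no isotype differed from the others (smallest adjusted p 0.902, Fisher's exact test). The place of an RNA gene made no detectable difference. A peak was at 14.1% of tRNA genes inside protein-coding genes and 15.6% of those between them (p = 0.65, Fisher's exact test), and at 9.22% and 14% of snoRNA genes (p = 0.213, Fisher's exact test). A B box was present at 98.9% of tRNA genes with a peak and 98.7% of those without. Among other non-coding RNA genes centred over 100 bp from any small RNA gene, it was at 10 of 27 with a peak (37%) and 12.3% of 7584 without (p = 0.000955, Fisher's exact test). Only 15 summits lay at other non-coding RNA genes alone, so these 27 genes can share summits and are not independent. The search covered the whole gene, and gene length was not matched, so no conclusion is drawn from this difference.

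For the leading pattern, the peaks at small RNA genes, reads shared between copies are argued against at snoRNA genes, where 97.3% of summit windows held no 36-base word found elsewhere, and stay open at tRNA genes, where 4.65% of windows (4 of 86) held none and repeated sequences had a peak in 16.4% of cases and single ones in 9.79% (odds ratio 1.81, exact 95% interval 0.974 to 3.58). High transcription of any gene is argued against as far as the ribosomal protein genes go, with 0 of 82 near a peak. Their upper bound was 4.4%, against a lower bound of 12.1% for tRNA genes. Transcription itself was not measured, so this covers those genes only. TAATTA or TAATTG sites are argued against by their presence in 1 of 129 windows (odds ratio 0.10, exact 95% interval 0.0025 to 0.609). The interval takes windows as independent, which those at tRNA genes are not. The core TAATGG was more frequent in these windows but was in only 11 of 129. That argues against it as the site at most of these peaks. A part for it at tRNA genes stays open. Those with it had a peak in 12.5% of cases and those without in 15.4% (odds ratio 0.788, exact 95% interval 0.385 to 1.5). RNA polymerase III promoters stay open too: a B box was at 26 of 38 snoRNA genes with a peak (68.4%) and 53 of 308 without (17.2%), but 6-mers of these summits had prompted that search, and among the 308 genes without one it was at 23.8% of the 84 with a lower-ranked pooled summit and 14.7% of the other 224 (odds ratio 1.80, exact 95% interval 0.913 to 3.51). Whether the tagged protein itself, or precipitation at such genes in any strain, gives the peaks stays open, since no untagged strain was analysed here.

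The excess on X was absent away from tRNA genes, and X carries 45.1% of those genes. The share of tRNA genes with a peak did not differ detectably between X and the autosomes (17.4% and 12.8%, p = 0.137, Fisher's exact test). The location of tRNA genes would give such an excess, but the rule set for this explanation left it undecided. Peaks away from tRNA genes were on X in 9.92% of cases (exact 95% interval 5.23 to 16.7%). The rule had asked that this interval include the 17.7% of the length, and it lay below. That lower share did not pass the chromosome test (adjusted p = 0.139, exact binomial test). More listed signal on X in general is argued against, since 15.2% of the rest of the pooled list was on X (exact 95% interval 14.8 to 15.6%). No biological explanation was tested.

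The stretch around ceh-9, 40.2 kb without a summit in any of the 3 ce11 lists in both replicates, could come from extra copies of the tagged region in the strain, but its copy number needs control reads that were not analysed here. Chance spacing stays open too, with 12 other stretches as long, which the first rule would have taken as chance; each had more repeated 36-base words, and the next shorter one (39.6 kb) had 5.17%. Unplaceable sequence is argued against, since 5.50% of the stretch's words occur elsewhere, under the 95th percentile of 26.6% for stretches of the same length that hold peaks, although the bound first set, the median of 4.79%, left it undecided.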
